A study of Drosophila melanogaster with 4 samples.

How the data were processed

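Genomic DNA of Drosophila melanogaster larvae was measured by targeted DamID in 4 samples, 2 with Dam alone and 2 with Dam-Pr-set7, each driven by grh-Gal4 and taken 24 h after larval hatching. Per the labels' protocols, DNA was cut with DpnI, which needs methylated GATC, the methylated fragments were amplified by PCR, libraries were made with a PCR-free Illumina kit and sequenced on a MiSeq. Per the submitters' processing notes, bcl2fastq 2.19.0.316, Bowtie2 2.2.6 and MACS 1.4.2 were used with genome build dm6. Whether the Dam-alone libraries served as the control in peak calling, and which cutoffs and duplicate filters were set, is not given in the sources used here. The deposited values are summit positions, each an interval of 1 bp, with a signal, the authors' pileup height in fragments at the summit, not scaled to depth. Peaks were called per sample, since each Dam-Pr-set7 sample has its own list. Peak widths, fold enrichments and p-values were not used here. Heights depend on the depth of each library. They were used to rank or select summits within a list, to compare X with autosomes within a list and to correlate paired summits, and the ratio of paired heights between replicates contains the unknown difference in depth.

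Groups were taken from the genotype in the labels. The labels give no replicate numbers, so replicates 1 and 2 are names in order of deposit, and do not pair samples across groups. Nothing states that the samples came from separate cultures of animals, and the p-values here measure the spread over summits or genes within these samples. Intervals are exact Clopper-Pearson 95% intervals for shares and cover counting error only; fragments amplified by PCR are not independent molecules. Precision is limited by the numbers of summits, 2876 and 4281, of which 2856 and 4240 lie on the 6 arms 2L, 2R, 3L, 3R, 4 and X that entered the comparisons. The other 20 and 41 were left out of them.

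Gene positions came from a RefSeq gene table of Release 6 plus ISO1 MT, the assembly that dm6 names, with start and end of 13922 protein-coding genes on the 6 arms. Gene strand, transcript starts, exons and the genome sequence were not used here. The tests had been designed around transcript starts and GATC sites, and were changed in 4 respects. A gene counted as reached when a summit lay within 1000 bp of either annotated end. Random placements used any position on the same arm in place of GATC sites. Expected numbers per arm followed arm length, up to the last gene end or summit, in place of GATC number. Features within genes were reduced to inside or outside the gene span. Distance of summits to GATC was not computed.

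Summits of the replicates were called shared within 500 bp, with 10000 random placements per arm. Gene ends were tested with 10000 placements, arms with exact binomial tests and heights with 100000 resamples. Fisher's exact tests were one-sided, for an excess, for the shared genes and two-sided for the 16 gene lists. Benjamini-Hochberg adjustment covered the 6 arms per replicate and the 16 lists, and the threshold was an adjusted p of 0.05. The lists held 727 terms, of which 30 were found through synonyms, 5 through an updated symbol and 12 not at all, giving 670 distinct genes. Their members, the comparisons, the distances, most alternatives and the naming of genes were set before the data were examined. Genes named are Cdk1, ebd1, Set8, grh, dpn, InR, CycE, stg, E2f1, wg and arm whatever their values, the 10 target genes with the highest mean height percentile with genes of the same summits counted as 1, up to 4 targets per list by the same measure, and every target of the cell cycle, Wnt and quiescence lists. The remaining DNA damage targets were named after their values were seen. Alternatives were distances of 200, 500, 1000 and 2000 bp, summits above the median height, circular shifts and local moves of summits (1000 each), replicates left out, gene spans, nearest ends, gene numbers per arm, lists without genes of other lists and 10000 matched random lists.

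Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used. The functions were tested on simulated data. In 100 simulated pairs of summit sets made to share 60% of positions, the overlap came out at 61.3% on average (60.8 to 61.9%). Shared positions were placed well within 500 bp, so an overlap of about 60% or more followed from the setting. Of the 100 sets, 4 gave a call in any gene list. Their summits lay at random positions, without the gathering at gene ends seen in the data. In 1 such set 706 genes were reached in both simulated replicates, against 1990 in the data. The rate of calls in these sets therefore need not hold for the lists tested here. All 200 of 200 planted genes were recovered among 13922, but their summits were planted inside the 1000 bp window, so recovery was certain. With the summits of the files and the share of 1 list at a time set to 30% or 40%, 49.4% and 83.8% of the lists were called.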

Results

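Targeted DamID was used to map where the histone H4 methyltransferase Pr-set7 (SETD8) sits on chromatin in larval neural stem cells of Drosophila, the progenitors that leave quiescence and re-enter the cell cycle after hatching. The Escherichia coli methylase Dam, alone or fused to Pr-set7, was driven by grh-Gal4 and marks the adenines of nearby GATC motifs, so that sequencing of the methylated DNA reads out positions the fusion protein visited. The 4 samples, taken 24 h after larval hatching, came from 2 batches with 1 Dam control and 1 Dam-Pr-set7 sample in each. The values described here are the summits called in the 2 Dam-Pr-set7 samples. The Dam-alone libraries were not analysed here, so no summit is compared with the Dam background. Replicate 1 had 2876 summits and replicate 2 had 4281, a ratio of 1.49. Their median heights were 42 fragments (range 12 to 279) and 37 fragments (range 11 to 204). Read depth per library is unknown, and each replicate is its own batch, so batch and replicate cannot be told apart. Heights levelled off at the top of the range, where 38 summits of replicate 2 lay within 10% of its maximum and 4 were at the maximum itself, against 14 and 1 in replicate 1.

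The question the study design puts first is which genes Dam-Pr-set7 reaches, and its title places these in the reactivation of neural stem cells. Among the genes fixed in advance, Cdk1, the mitotic kinase, and ebd1, which encodes the Wingless pathway cofactor Earthbound 1, had a summit within 1000 bp of an annotated end in both replicates. At ebd1 (3L, 682885 to 685549, dm6) the highest summits, at 685364 with 106 fragments in replicate 1 and at 685376 with 131 in replicate 2, lay inside the gene and 12 bp apart. The replicate 1 summit at 685364 was also within 1000 bp of hiro. A further pair at 682212 (64 fragments) and 682233 (89 fragments), 21 bp apart, lay beyond the other end of ebd1. At Cdk1 (2L, 10384739 to 10386262) the summit of replicate 1 within 1000 bp of an end was inside the gene at 10385804 with 42 fragments, and that of replicate 2 was 181 bp outside it at 10386443 with 73 fragments. These 2 positions were 639 bp apart, more than the 500 bp used to call summits shared, and the latter falls between Cdk1 and its neighbour mRpS7, a mitochondrial ribosomal protein gene. Further summits lay 2100 bp from Cdk1 in replicate 1 (10388362, 75 fragments) and 1498 bp from it in replicate 2 (10387760, 38 fragments).

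The other fixed genes had no such pair of summits. Set8, the gene of Pr-set7 itself, had none in replicate 1 and 2 in replicate 2, with 39 fragments at 271 bp outside the gene and 104 fragments inside it. The Dam-Pr-set7 samples also carry Pr-set7 as a transgene, whose reads were not separated from those of Set8. The summit inside Set8 therefore need not show binding at the native gene. For arm, which encodes the Drosophila beta-catenin, summits were inside the gene in both replicates, at 1893878 (100 fragments) and 1899417 (20) in replicate 1 and at 1899487 (56) in replicate 2 on X, each more than 1000 bp from its ends. The insulin receptor gene InR carried an internal summit in replicate 1 (21581687, 43 fragments) and 3 internal summits in replicate 2, plus 1 of 16 fragments at 598 bp outside it. E2f1, a transcription factor of S-phase entry, had a summit at 833 bp from its end in replicate 1 (25 fragments), whereas the internal summit of replicate 2 (24 fragments) was 2451 bp away. The neural stem cell transcription factor gene grh, which gives the driver its name, had 2 internal summits in replicate 2 and 0 in replicate 1, and CycE (cyclin E) had 1 and 0. Whether the driver itself carries grh sequence was not analysed here. No summit of either replicate lay within 3000 bp of dpn, a stem cell marker, of stg, the Cdc25 phosphatase of mitotic entry, or of wg, the Wingless ligand gene. A missing summit means that none was called at this depth, not that the protein was absent.

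**Figure D1:**
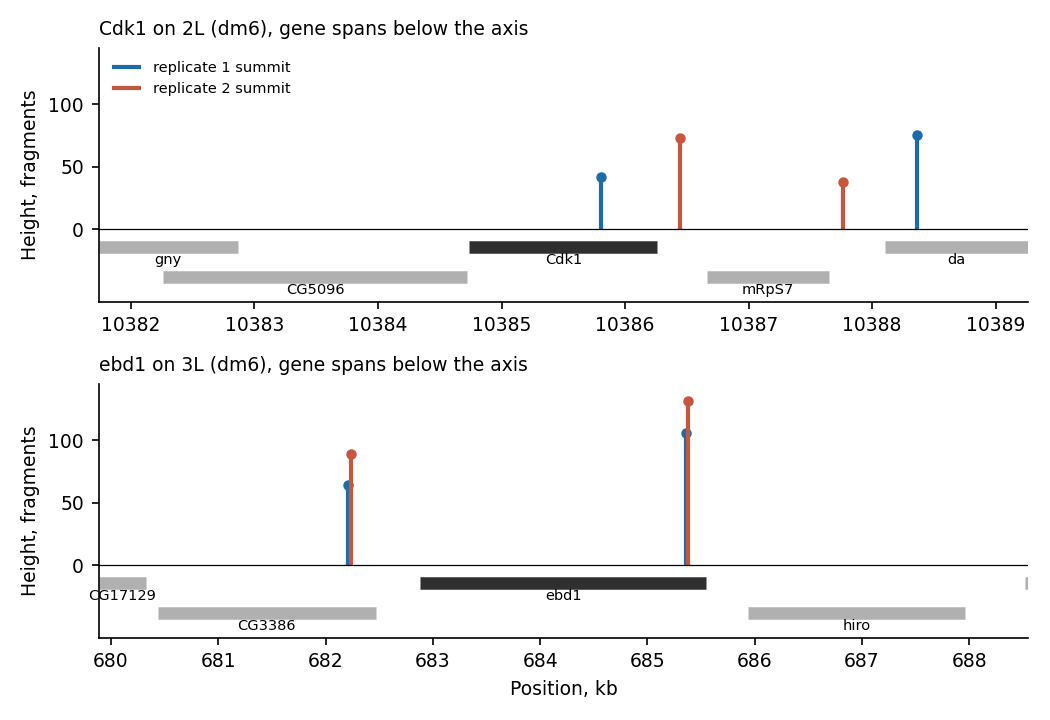
Summits of replicate 1 (blue) and replicate 2 (red) around Cdk1 and ebd1, with position in kb on the horizontal axis, summit height in fragments on the vertical axis and spans of protein-coding genes as bars below. The ebd1 summits of the replicates lie 12 bp and 21 bp apart, and the pair within 1000 bp of an end of Cdk1 lies 639 bp apart.

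Across the genome, 1990 of 13922 protein-coding genes (14.3%) had a summit within 1000 bp of either end in both replicates, called target genes from here on. The highest paired summits belonged to CG13295 and CG6610, neighbours on 3L that share a summit at 6075566 with 279 fragments in replicate 1 and 204 in replicate 2. Next came EMC8-9 with YME1L on 2R (276 and 204 fragments), where YME1L encodes a mitochondrial protease. They were followed by CG34140, Mkp and Mtch on 3L, which share a summit with 268 and 204 fragments. The remaining 7 places of the first 10 were held by Pop4 with nmo (251 and 204), CG4133 (256 and 203), yrt (255 and 200), Mst85C (258 and 194), IKKbeta with CG5013 (237 and 196), Aps (233 and 202) and Fdh with CG4596 (231 and 194 fragments). Of these, nmo encodes the Nemo kinase, yrt the epithelial polarity protein Yurt and IKKbeta a kinase of the innate immune response. The replicates on their own had 2546 and 3130 genes with such a summit, so that independent lists would share 572.4. The observed number was 3.48 times that (one-sided Fisher's exact test, odds ratio 32.1, log10 of p = -1040). This test counts genes as independent although many share summits, and it ignores that both replicates gathered at gene ends. Its p therefore overstates the evidence. In 1798 target genes (90.4%) the highest summits of the replicates lay within 500 bp of each other. Because Drosophila genes lie close together, 1584 target genes (79.6%) shared their replicate 1 summit with at least 1 other gene, and the 1990 genes rest on 1180 summits of replicate 1 and 1178 of replicate 2. When each summit was counted only for the gene with the nearest end, 1121 genes remained.

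Genes of the cell cycle list carried target summits in 13 of 51 members (25.5%, 95% exact interval 14.3 to 39.6%), against 14.3% of the other genes. These included dpa (183 and 176 fragments in replicates 1 and 2) and Mcm2 (98 and 147), subunits of the replicative helicase, Psf2 of the GINS complex (167 and 188) and Orc2 of the origin recognition complex (32 and 46). The others were the kinases Cdk1, Cdk2, aurA and aurB, the cyclin CycA, the retinoblastoma homologue Rbf, the checkpoint kinase BubR1, the chromosomal passenger borr and the APC/C activator cort. For aurB, as for Cdk1, the highest summits of the replicates lay more than 500 bp apart. The replicate 1 summits of dpa, Psf2, Mcm2 and Orc2 lay outside these genes. They were also within 1000 bp of CG1620, Vps53, RPA1 and Kots, respectively. The cell cycle share was not called over the 16 lists (Fisher's exact test, two-sided, p = 0.0415 before adjustment, 0.186 with Benjamini-Hochberg adjustment over all lists). It was called within 2000 bp (37.3% against 20.6% of other genes; Fisher's exact test, adjusted p = 0.0434), in replicate 2 alone (45.1% against 22.4%, 0.00507) and with a summit in either replicate (52.9% against 26.4%, 0.00127). Its fold over other genes was then 1.81, 2.01 and 2.01, against 1.79 here. It was not called in replicate 1 alone, within 500 bp or above the median height (adjusted p = 0.0784, 0.201 and 0.191 with Fisher's exact test). Nor was it called by gene span, by nearest end or without genes of other lists (Fisher's exact test, adjusted p = 0.0612, 0.31 and 0.136). By nearest end 17.6% were targets, against 8.02% of other genes. Against random lists matched on length and transcripts or on neighbouring gene ends and length it was not called either (adjusted permutation p = 0.458 and 0.495). Wnt/Wingless genes gave 11 of 43 targets (25.6%, interval 13.5 to 41.2%), likewise not called (Fisher's exact test, p = 0.0465, adjusted p = 0.186) except with summits anywhere in the gene span (37.2% against 18.1%, adjusted p = 0.0146). By nearest gene end the Wnt share was 9.30% against 8.05% (Fisher's exact test, adjusted p = 1), a fold of 1.16 against 1.79 here. Within 500 bp it was 11.6% against 8.83% (Fisher's exact test, adjusted p = 0.853), a fold of 1.32. Against the 2 kinds of matched lists the adjusted permutation p were 0.475 and 0.495. The Wnt targets comprised nmo, the TCF factor pan (171 and 170 fragments), Tnks (121 and 119), ebd1, the acetyltransferase nej (80 and 85), Axn (74 and 77), Apc (21 and 35), slmb, lic, gish and Wnt2. For gish and Wnt2 the highest summits of the replicates lay at opposite ends of the gene. For pan the highest summit was 594 bp inside the gene in replicate 1 and 324 bp outside the same end in replicate 2. These pan summits lay more than 500 bp apart. The list of quiescence and reactivation genes had 6 of 34 targets (17.6%, interval 6.76 to 34.5%, adjusted p = 0.857 with Fisher's exact test). These were Patronin (129 and 165 fragments), which binds microtubule minus ends, Cul4 (160 and 128), nab (82 and 80), mts (52 and 42), Golgin84 (37 and 36) and Fas2 (17 and 18). The replicate 1 summits of all but Fas2 also lay within 1000 bp of other genes, such as udd for Cul4 and Rack1 for mts. By nearest gene end the share was 8.82% against 8.05% of other genes. The Fas2 summits were among the lowest, at height percentiles of 5.20 and 13.5.

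DNA damage response genes were the 1 list called, with 13 of 38 members targeted (34.2%, interval 19.6 to 51.4%) against 14.2% of the other genes (Fisher's exact test, odds ratio 3.13, p = 0.00164, adjusted p = 0.0263). Its members with the highest summits were tefu, the ATM kinase gene (90 and 138 fragments), okr, a Rad54 homologue (86 and 84), the helicase gene Blm (77 and 80) and the nucleotide excision repair gene mus201 (69 and 64). The other targets were Brca2, DNAlig4, Parp1, Rad9, grp, hay, mei-9, mus301 and rad50. The call was lost within 500 bp, with summits above the median height, in replicate 2 or replicate 1 alone and with a summit in either replicate (Fisher's exact test, adjusted p = 0.243, 0.0686, 0.12, 0.0784 and 0.218). It was also lost when each summit counted only for the nearest gene end (13.2% against 8.04%, adjusted p = 0.408 with Fisher's exact test). Against random lists matched on neighbouring gene ends and length, or on length and transcripts, it was lost too (adjusted permutation p = 0.138 and 0.08). The call held within 2000 bp (42.1% against 20.6% of other genes) and without genes of other lists (35.1% against 14.2%). The adjusted p with Fisher's exact test were 0.0373 and 0.0199. Summits of tefu, okr, Blm and mus201 also lay within 1000 bp of Hsc70-4, CG3558, CG14722 and Chrac-14, respectively.

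Insulin, PI3K and TOR genes had 9 of 35 targets (25.7%; adjusted p = 0.269 with Fisher's exact test), among them Pi3K92E (126 and 149 fragments), dock (117 and 110), Pdk1 (96 and 113) and REPTOR-BP (85 and 94). Genes of histone methylation and the Polycomb and trithorax groups had 10 of 48 (20.8%; adjusted p = 0.502 with Fisher's exact test), led by the insulator protein gene CTCF (200 and 185) and l(3)mbt (171 and 143). The highest l(3)mbt summits of the replicates lay more than 500 bp apart. Ribosomal protein genes had 16 of 92 (17.4%; RpL39 had 156 and 152 fragments), Notch and EGFR genes 6 of 39 (15.4%; mam had 219 and 182 fragments), Hippo genes 5 of 33 (15.2%; sav and Cul4 came first, with summit height percentiles of 98.6 and 94.9 averaged over the replicates) and temporal factors 5 of 33 (15.2%; lin-28 had 167 and 139). Hox and patterning factors had 8 of 62 (12.9%), including tsh (156 and 136), tup (125 and 115) and Antp (135 and 106). Stem cell identity genes had 3 of 41 (7.32%), which were cnn (100 and 130, more than 500 bp apart), Galphai (97 and 106) and aurA (108 and 92). For none of these 6 lists did the share pass the threshold with Fisher's exact test, with adjusted p from 0.53 to 0.857. With summits anywhere in the gene span, temporal factors (39.4% against 18.2% of other genes), histone methylation genes (37.5% against 18.1%) and neuron markers (38.5% against 18.1%) were called (Fisher's exact test, adjusted p = 0.0179, 0.0146 and 0.0146). Histone methylation genes were also called within 2000 bp (37.5% against 20.6%; Fisher's exact test, adjusted p = 0.0434). A longer span can hold more summits, and these gene span calls were not matched for length. DNA damage genes were called by gene span as well (36.8% against 18.2%; Fisher's exact test, adjusted p = 0.0179). Median lengths of the called lists were 21120 bp for neuron markers, 17167 bp for temporal factors, 9246 bp for Wnt, 5571.5 bp for histone methylation and 3457 bp for DNA damage genes. The middle quintile of all genes had 2161.5 bp. Hox and patterning factors (12177 bp; 25.8%) and muscle markers (11904 bp; 11.8%), against 18.2% of other genes each, were not called by gene span (Fisher's exact test, adjusted p = 0.242 and 0.62). Among markers of other cell types, neuron genes had 6 of 39 targets (15.4%, such as nSyb with 69 and 97 fragments), glia genes 3 of 37 (8.11%, such as Nrx-IV with 122 and 133), muscle genes 2 of 34 (5.88%, how and Obsc) and epidermis and trachea genes 1 of 42 (2.38%, Cht2). The epidermis and trachea share lay below that of the other genes before adjustment only (Fisher's exact test, p = 0.0245, adjusted p = 0.186). With lists of this size a true share of 40% was called in 83.8% of simulated lists and a true share of 30% in 49.4%. Smaller departures were not simulated.

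**Figure D2:**
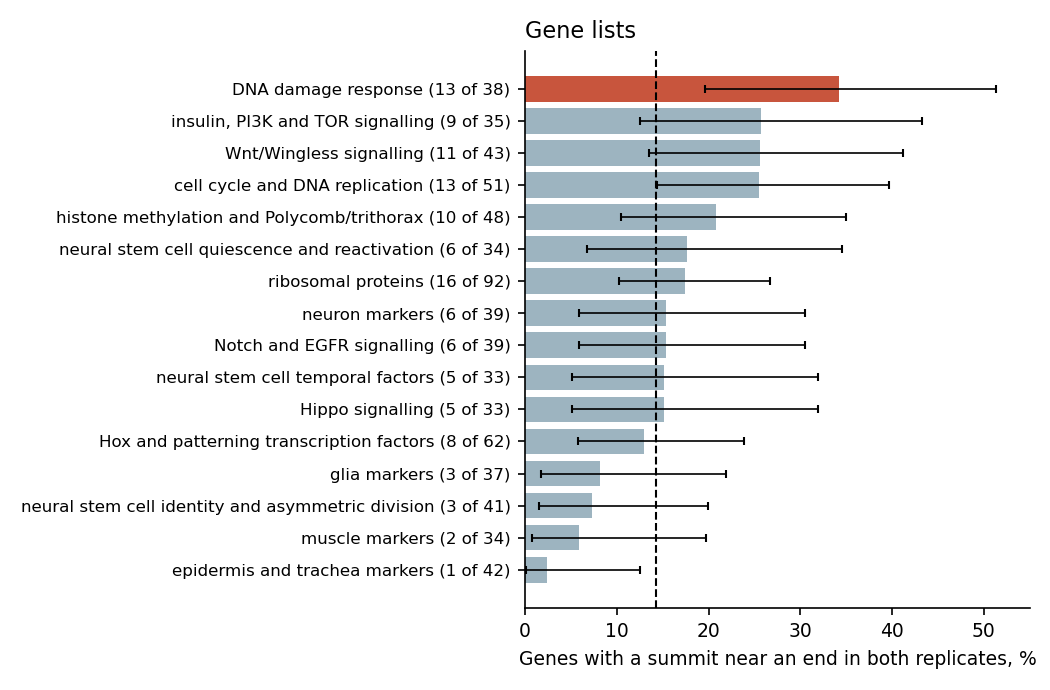
Share of each gene list with a summit within 1000 bp of a gene end in both replicates, in percent, with 95% exact binomial intervals; the numbers after each name are targets and members, and the dashed line marks the 14.3% of all protein-coding genes. DNA damage response (red, 34.2%) is the list with an adjusted p under 0.05 in the Fisher test, and epidermis and trachea markers have the lowest share, 2.38%.

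Gene ends were where the summits gathered, in both replicates. In replicate 1, 1551 of 2856 summits on the chromosome arms (54.3%, interval 52.5 to 56.1%) lay within 1000 bp of an end of a protein-coding gene. In replicate 2 it was 2057 of 4240 (48.5%, interval 47.0 to 50.03%). Random positions on the same arms gave 24.7% for each. The rise was steepest in the 250 bp just outside the ends, with 3.71 times the random share in replicate 1 and 3.05 times in replicate 2, and in the first 250 bp inside it was 2.64 and 2.26 times. The two-sided permutation p was 0.0002 in each replicate, the smallest that 10000 placements can give. When each summit was moved only 5000 to 50000 bp, 30.2% and 29.6% lay within 1000 bp of an end. The excess at gene ends was therefore smaller against local moves than against random positions, but it remained in both replicates. Without the Dam-alone libraries, gathering at gene ends cannot be assigned to Pr-set7 rather than to Dam itself. Starts and 3' ends of genes were not told apart here, since gene strand was not used, and exons, introns and UTRs were not assigned. Summits inside gene spans made up 69.5% and 69.6%, against 67.2% and 67.1% of random positions (permutation p = 0.0086 and 0.0008). That small excess turned into a deficit when each summit was moved only 5000 to 50000 bp, which gave 73.3% and 72.8%.

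**Figure D3:**
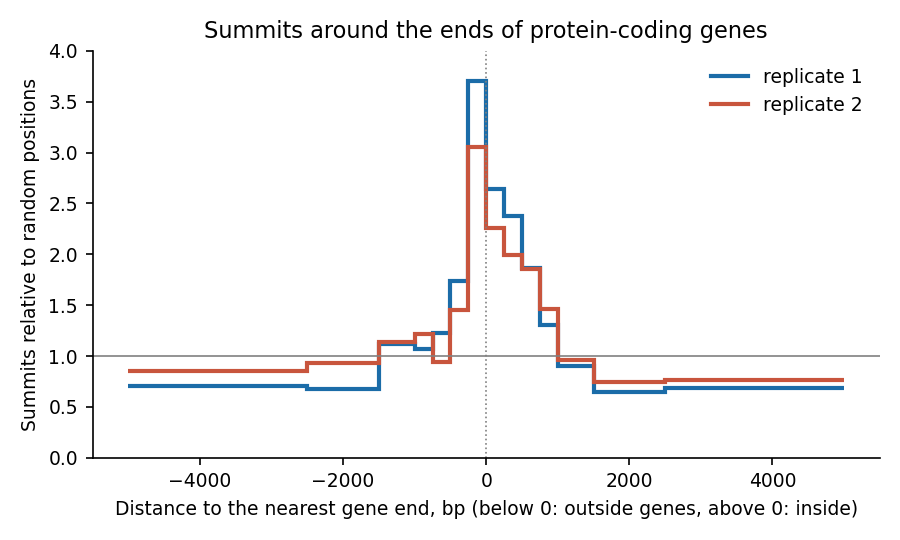
Number of summits relative to random positions on the same arm (vertical axis, 1 means as many as at random) by distance in bp to the nearest end of a protein-coding gene, outside genes to the left of 0 and inside to the right. Both replicates (blue, 1; red, 2) peak in the 250 bp just outside the ends, at 3.71 and 3.05.

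The X chromosome held fewer summits than its length and the small chromosome 4 held more, in each replicate. Replicate 1 had 404 summits on X, 0.803 times the number expected from arm length (95% exact interval 0.732 to 0.879; exact binomial test, adjusted p = 4.08e-06). Replicate 2 had 504, or 0.675 times (interval 0.620 to 0.732; exact binomial test, adjusted p = 6.97e-24). Chromosome 4, rich in heterochromatin, had 51 and 67 summits, 1.81 and 1.60 times the expected number (exact binomial test, adjusted p = 0.000264 and 0.000644). Of the 67 in replicate 2, 22 were shared with replicate 1, against 46.5% of replicate 2 summits over all arms. Arms 2L (1.10 and 1.15 times) and 2R (1.12 and 1.09 times) lay above expectation with adjusted p of 0.0238 and 2.62e-05 and of 0.0041 and 0.00804 in the exact binomial test, but these calls were lost when gene number replaced length. Arms 3L (0.974 and 0.981 times) and 3R (0.966 and 1.05 times) were not called.

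The replicates shared most of the higher summits. Within 500 bp, 1972 of the 2856 summits of replicate 1 (69.0%, interval 67.3 to 70.7%) had a summit of replicate 2, and 1973 of the 4240 summits of replicate 2 (46.5%, interval 45.0 to 48.0%) had a summit of replicate 1. Random positions gave 3.19% and 2.18%, so the overlap was 21.7 and 21.4 times higher (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). Paired summits lay a median of 22 bp apart, and 93.6% of those of replicate 1 were within 100 bp. From the lowest to the highest quintile of height the shared part went from 57.2% to 83.0% in replicate 1 and from 13.3% to 81.0% in replicate 2. Shared summits were also more often at gene ends than the rest, with 56.6% against 49.1% in replicate 1 and 56.6% against 41.5% in replicate 2 (Fisher's exact test, p = 0.000186 and 1.34e-22). Height was not held fixed in this comparison. Summits above the median height lay at gene ends in 61.3% and 57.7%, against 54.3% and 48.5% of all, so sharing and height cannot be told apart.

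**Figure D4:**
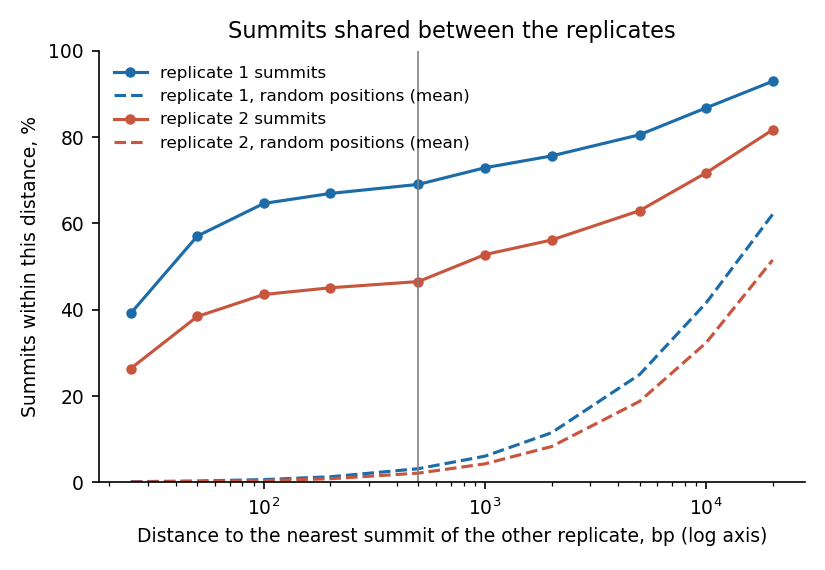
Percent of the summits of each replicate (blue, 1; red, 2) with a summit of the other replicate within the distance in bp on the log-scaled horizontal axis; dashed lines give the mean for random positions and the grey line marks 500 bp. At that distance 69.0% and 46.5% are shared, against 3.19% and 2.18% at random.

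Heights of the 1972 summit pairs rose together, with Pearson's r = 0.88 on log2 heights and Spearman's rho = 0.88 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The correlation is across summits, which are not independent replicates. In 1324 pairs the summit was higher in replicate 2 and in 595 in replicate 1, with a median log2 ratio of replicate 2 to replicate 1 of 0.19.

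**Figure D5:**
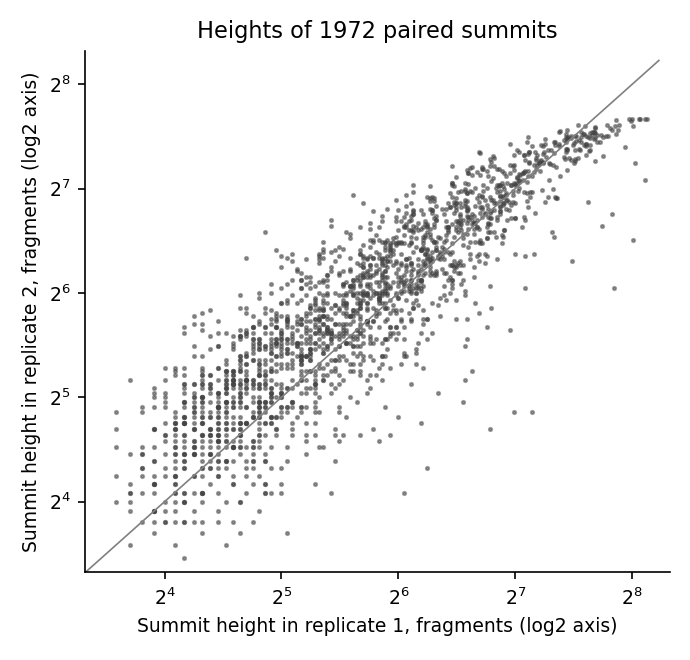
Height in fragments of 1972 paired summits in replicate 1 (horizontal, log2 axis) and replicate 2 (vertical, log2 axis); each point is a pair and the line marks equal heights. Heights rise together (Spearman's rho = 0.88), and the points of replicate 2 level off at its maximum of 204.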

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

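The tests in this part were chosen only after the summits outside the chromosome arms had been seen. Summits outside the 6 arms, which no comparison used, numbered 20 in replicate 1 and 41 in replicate 2. The unplaced scaffold with the most summits held 8 in replicate 1 and 14 in replicate 2 over 35.2 kb. This is 2.27 and 3.98 per 10 kb against 0.214 and 0.317 on the arms, and all 8 of replicate 1 lay within 28 bp of a summit of replicate 2. Another unplaced scaffold held 3 and 5 summits, of which the highest reached 171 fragments in replicate 1 and 108 in replicate 2. Replicate 1 had 3 summits on scaffolds assigned to Y, with 112, 26 and 18 fragments, and replicate 2 had 1 on such a scaffold and 3 on Y itself, of at most 16 fragments. Replicate 2 also had 2 summits on the mitochondrial genome, and replicate 1 had 0. No explanation of these summits was tested, and copy number in repeated sequence was not analysed here.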

How the results depend on the processing

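Local moves, gene numbers per arm, nearest ends and the 2 kinds of matched random lists were chosen only after the data had been seen; the other alternatives were planned. Replicate overlap (45.1 to 74.1%), summits at gene ends (33.9 to 64.3%), the deficit on X (0.616 to 0.896 times), the excess on chromosome 4 (1.60 to 3.11 times) and the height correlation (rho 0.81 to 0.88) kept direction and call under every alternative run. Unless stated, causes of the changes below were not tested. With only summits above the median height, 2L of replicate 1 (1.07 times) and 2R (1.12 and 1.08) lost their calls, with fewer summits, and 3L of replicate 1 reversed without a call (1.01). With gene numbers, 2L (1.01 and 1.06) and 2R (1.04 and 1.01) lost theirs and 3L reversed without a call (1.04 and 1.05). Summits inside genes in replicate 1 (69.5%) lost the call with circular shifts (permutation p = 0.0579), and both replicates (69.5 and 69.6%) reversed under local moves, against 73.3 and 72.8%. Target genes numbered 1990, but 1230 at 500 bp, 1204 above the median height, 2546 to 3130 with a replicate left out, 3686 with a summit in either replicate and 1121 by nearest end. The number of lists called, 1, became 0 at 500 bp, above the median height, by nearest end and against either kind of matched lists, 3 at 2000 bp, 5 with gene spans, and 0 to 1 with a replicate left out. The DNA damage list was no longer called at 500 bp (18.4% against 8.81% of other genes), above the median height (23.7 against 8.61%), with a replicate left out (36.8 to 39.5% against 18.2 to 22.4%), with either replicate (42.1 against 26.4%), by nearest end (13.2 against 8.04%) and against lists matched on transcripts or on neighbours (34.2% in each, against 15.5 and 17.2%), with adjusted p from 0.0686 to 0.408 in these settings. Its fold was 2.40 in the report, 2.09 at 500 bp, 2.75 above the median height, 1.76 and 2.02 without replicate 1 or 2, 1.59 with either replicate and 1.64 by nearest end. The cell cycle list became called at 2000 bp (37.3 against 20.6%), with replicate 2 alone (45.1 against 22.4%; replicate 1 alone, not called, 33.3 against 18.2%) and with either replicate (52.9 against 26.4%), at folds of 1.81 to 2.01 against 1.79. Histone methylation genes became called at 2000 bp (37.5 against 20.6%) and with gene spans (37.5 against 18.1%), which also called Wnt (37.2%), temporal factors (39.4%) and neuron markers (38.5%). The other changes were reversals of lists that were called neither way, with adjusted p from 0.242 to 1. For gene spans they were Hippo (18.2%), stem cell identity (22.0%), Hox (25.8%), glia (21.6%) and ribosomal genes (17.4%). For nearest ends they were Hippo (6.06%), Hox (12.9%), neuron (7.69%), glia (8.11%) and ribosomal genes (3.26%). At 500 bp they were Notch and EGFR (2.56%), Hox (12.9%), neuron (7.69%) and ribosomal genes (6.52%), at 2000 bp Notch and EGFR (20.5%) and Hox (21.0%), and above the median height Notch and EGFR (5.13%) and neuron (7.69%). Leaving out replicate 2 turned Hippo (18.2%), Hox (21.0%) and neuron (17.9%), whereas leaving out replicate 1 did not (24.2, 16.1 and 23.1%), a summit in either replicate turned neuron (25.6%), and leaving out genes of other lists turned Hippo (12.5%) and temporal factors (12.5%). Lists matched on transcripts turned Hippo (15.2%), temporal factors (15.2%), Notch and EGFR (15.4%) and neuron (15.4%), and those matched on neighbours Hippo (15.2%), Hox (12.9%) and neuron (15.4%). No paired analysis was possible because only the Dam-Pr-set7 group was analysed. GATC-based placements and lists, and the most upstream start, were not run. Unknown depth limits what a missing summit says.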

Other observations

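All tests in this part were chosen after the data had been seen, except that the predictions for matched gene neighbourhoods and for the flanks of w were written before those results. Several gene families were rarely targeted. Of the cuticular protein genes 2 of 110 (1.82%) had a summit near an end in both replicates, of olfactory and gustatory receptors 4 of 119 (3.36%), of cytochromes P450 4 of 85 (4.71%) and of glutathione and UDP-glycosyl transferases 2 of 70 (2.86%). Each share was below that of other genes over 23 families (Fisher's exact test, adjusted p = 0.000314, 0.00199, 0.044 and 0.0234), and also below random lists matched on neighbouring gene ends and length (adjusted permutation p = 0.0046, 0.023, 0.0253 and 0.0253). These tests count each gene as independent. Members of a family that lie side by side can lack summits together, and the lists were not matched for such clustering. With each summit counted for the nearest end only, the shares were 0.909, 2.52, 1.18 and 0%, against 8.09 to 8.11% of other genes. The calls were then lost (Fisher's exact test, adjusted p = 0.0502, 0.147, 0.109 and 0.0722), with fewer target genes in all. No family lay above the other genes after adjustment, although nucleoporins had 7 of 21 (33.3%, Fisher's exact test, adjusted p = 0.0789) and mitochondrial ribosomal proteins 17 of 73 (23.3%, adjusted p = 0.0961). Among genes without protein products, tRNA genes had 5 of 290 (1.72%), snoRNA genes 14 of 269 (5.20%), lncRNA genes 118 of 1959 (6.02%) and miRNA genes 17 of 260 (6.54%), against 14.3% of protein-coding genes (Fisher's exact test, adjusted p from 3.15e-27 to 0.000205). Pseudogenes had 20 of 245 (8.16%, adjusted p = 0.00626) and rRNA genes 0 of 98, whereas antisense RNA genes, with 67 of 503 (13.3%), were not called (Fisher's exact test, adjusted p = 0.603). These comparisons of gene types were not matched for length, neighbours or clustering. Among protein-coding genes the share was 9.07% in the quintile of shortest genes and 8.26% in that with the fewest neighbouring gene ends.

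The bithorax complex from Ubx to Abd-B (3R, 16656623 to 16972236) held 17 summits in replicate 1 and 46 in replicate 2, or 5.39 and 14.6 per 100 kb against 2.14 and 3.17 on the arms. The Antennapedia complex from lab to Antp held 13 and 26, or 3.85 and 7.70 per 100 kb. Of the replicate 2 summits, 14 of 46 in the bithorax complex and 9 of 26 in the Antennapedia complex were shared with replicate 1. The replicates differed at the bithorax complex before adjustment only (Fisher's exact test, p = 0.0381, adjusted p = 0.191 over 5 regions). The Enhancer of split complex had 0 and 1 summits over 52.3 kb and the engrailed and invected region 0 and 1 over 53.7 kb. Neither was called (exact binomial test, unadjusted p = 0.634 and 1, and 0.636 and 1). At the rates of the arms so few summits are expected in these regions that even 0 could not show a deficit. Of the highest 10% of summits, 42 of 287 in replicate 1 and 46 of 424 in replicate 2 had no partner within 2000 bp. Examples chosen after their values were seen are Trx2 (260 fragments) and v (237) in replicate 1 and Rbp6 (161) and CycB (127) in replicate 2.

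Fewer summits on X were found than its length predicts. A lower number of genes there did not account for all of it, since against gene counts the ratios were still 0.896 in replicate 1 and 0.753 in replicate 2, with adjusted exact binomial p of 0.0475 and 2.21e-12. A lower read depth on X, which a share of male larvae could bring, remains open. The median X summit was 0.919 times as high as the autosomal one in replicate 2 (bootstrap interval 0.842 to 1) and 0.942 times in replicate 1 (0.837 to 1.05), and neither interval settles it. Summits assigned to Y or its scaffolds were called in both replicates, 3 in replicate 1 and 4 in replicate 2, which does not measure depth on X, and no biological explanation was tested.

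The excess of DNA damage response genes among the targets could come from summits that belong to close neighbours, which the tests leave open. With each summit counted for the nearest end only, 13.2% of the list were targets against 8.04% of other genes, and the call ended (Fisher's exact test, adjusted p = 0.408). The fold over other genes was then 1.64, against 2.40 with all summits, and 5 targets are too few to tell these apart. Against random lists matched on neighbouring gene ends and length, whose mean was 17.2% with 95% of lists from 5.26 to 28.9%, the observed 34.2% lay above the range but had an adjusted p of 0.138 over the 16 lists. Gene density and length can therefore neither be excluded nor shown as the source.

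The eye colour gene w (X, 2790599 to 2796466) carried 2 summits in replicate 1, with 222 and 187 fragments, and 0 in replicate 2. Extra copies of a w marker fragment in the batch of replicate 1, such as transgenes often carry, are a candidate explanation that stays untested. In the 20000 bp on either side of w, there were 0 summits found in replicate 1 alone, but only 0.265 of these were expected there, so this count decides nothing. Vector sequence carried by each Dam-Pr-set7 sample would be found in both replicates unless the control removed it, and the 0 summits in w of replicate 2 cannot decide this without the Dam-alone libraries. The marker of each fly stock was not analysed here, and no biological explanation was tested.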
